A study of Rattus norvegicus with 20 samples.

How the data were processed

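RNA from cultured rat microglia was sequenced in 20 libraries, 4 for each of PBS, morphine, LPS, PAM3CSK4 and zymosan. Per the labels' protocols, CD11b-positive cells were immunopanned from perfused brains of rats aged 21 days, with the cerebellum discarded, cultured in serum-free medium for 5 days and treated in a 50% medium change. RNA was extracted with RNeasy Micro columns, and libraries were made with Smart-Seq2 and Nextera XT. The protocol also names a morphine dose of 10 uM, and only the 1 uM samples were analysed here. The authors deposited FPKM values, that is, fragments per kilobase of transcript scaled to the library's mapped fragments, in 1 table of gene symbols, without counts. The submitters' processing notes name HISAT2 2.0.5.1, Cufflinks 2.2.1, featureCounts 1.4.6 and DESeq2 and the rat genome build rn6, with no role or order for each tool, and the annotation is not given in the sources used here. Groups and replicate numbers were taken from the labels. The labels do not say whether the 4 libraries of a group came from separate cultures or animals, so that the p-values measure only the spread between these samples, which may be technical.

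FPKM is relative to each library's own total. A large rise in some genes lowers the FPKM of all others, and without counts neither depth nor counting error is known. An exact 0 in the table can be a failed estimate: 41 values in 21 genes were 0 where the other 3 libraries of the group were at 5 FPKM or more. Such genes are given per library where they are named. The symbols, in capitals in the table, were matched to the RefSeq gene table of assembly GRCr8, 14814 by symbol and 2113 by synonym, for spelling only; no coordinates were used. Reads shared between near-identical genes, such as Calm2 and Calm3 or the RT1 genes, could be split by the authors' counting in ways the values do not show, so those genes are uncertain.

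Values were tested as log2(FPKM + 1), with a pseudocount of 1 FPKM, over the 8858 genes with at least 1 FPKM in at least 4 libraries. A linear model with 5 group means was fitted to all 20 libraries at once in limma 3.58.1 (R 4.3.3), with moderated variances and a mean-variance trend. Contrasts of each treatment with PBS, of the TLR agonists with each other and of morphine with LPS were tested two-sided, and p-values were adjusted by Benjamini and Hochberg within each contrast; an adjusted p under 0.05 was called. Fold changes on this scale understate those of low genes. Gene lists, 34 in all, were fixed before the data were examined, and the 27 with at least 5 tested genes were tested with limma's rotation test fry, which asks whether the genes of a list moved on balance one way and does not compare the list with other genes. Camera, which does, was run with a preset correlation of 0.01 and with an estimated correlation. Results given below with an estimated correlation are those of camera. A fry call said to be lost there was not made by camera, which asks another question. The calls of single members are not changed by it. Every list p-value and adjusted p in the text comes from these limma functions. Python 3.11.15 and matplotlib 3.10.9 drew the plots.

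Genes named in the text were chosen by a rule fixed before the data were examined: the 10 largest increases and decreases among called genes whose groups did not overlap and whose higher mean was at least 5 FPKM; where fewer than 5 were called, the 5 smallest p-values; 2 to 4 examples of each list; and a fixed set of inflammatory, receptor, microglial and opioid receptor genes. Other genes are said to have been chosen after their values were seen, and include Creb3, Psma3 and Rn18s as examples of listed zeros.

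The library sets were found in the data as the first principal component of what remained after the group means were removed. Fits using them were therefore chosen after the data had been seen. A set term takes out part of the spread that defined it, so p-values with it may be too small. Alternatives were a pseudocount of 0.1 FPKM, no filter on low values, median-ratio rescaling of the libraries, library quality weights, the replicate number as a block, only the 2 groups compared in the fit, both camera tests, and leaving out each library in turn. The alternatives added later were a library-set term, fits within either set and exact zeros treated as missing. The same fit was tested on simulated data with 200 changed genes among 8858. For morphine against PBS it recovered 48.6% of 2-fold and 93% of 4-fold changes, and with the set term 87.8% and 98.6%, with 0.701% and 5.28% of calls false. For LPS against PBS it recovered 50.8% of 2-fold and 94.4% of 4-fold changes. A list of 20 genes that all rose 2-fold was called in 20 of 20 simulations of the morphine comparison. Smaller or mixed shifts of a list were not simulated. In these simulations the changed genes were drawn from those above a floor on the mean level. Noise was independent between genes, and the set term was given the true sets. The real data lack these settings, so the shares recovered there may be lower and the false shares higher. For the shared PBS libraries, 100 sets of unchanged groups with shared controls were simulated, with their correlations and shared calls. All groups, controls included, were drawn from all 20 libraries after the group means were removed. The PBS libraries were also split in 6 ways. The replicate numbers were taken to pair the libraries of a comparison where all 4 correlations between libraries of the same number, after the group means were removed, were over 0.1. This held for PAM3CSK4 and for zymosan against PBS, zymosan against PAM3CSK4 and morphine against LPS (lowest r 0.375, 0.318, 0.525 and 0.553). It failed in the other 4 comparisons, where the libraries with number 2 lay in different library sets (lowest r −0.139 for morphine and −0.186 for LPS against PBS, −0.259 for PAM3CSK4 and −0.279 for zymosan against LPS). The pairing rests on the data alone, since the labels state no shared animal, culture or day, and was judged for each comparison by this rule alone, after the fits had been run. Within a library set, libraries of the same number correlated at a mean of 0.569 and those of different numbers at 0.298. The rule mostly tells whether libraries of the same number lie in the same set (mean r 0.405 within a set and −0.443 between sets). For morphine against LPS, libraries of different numbers in the same set correlated at 0.286 to 0.579, so wrong pairs would pass too. Below, paired and unpaired numbers mean only that the rule was met or not.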

Results

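Transcript levels were measured by RNA sequencing in cultured rat cortical microglia, the resident macrophages of the brain. The cells came from male Sprague-Dawley rats aged 21 days, were purified by immunopanning on CD11b, a surface integrin of myeloid cells, and were kept in serum-free medium for 5 days. They then received PBS, morphine (1 uM), an opioid receptor agonist, or 1 of 3 agonists of Toll-like receptors (TLRs), which sense microbial products. These were LPS (1 ng/mL), bacterial endotoxin sensed by TLR4, PAM3CSK4 (1 ng/mL), a synthetic lipopeptide sensed by TLR2 with TLR1, and zymosan (100 ug/mL), a yeast cell wall preparation sensed by TLR2 and dectin-1. Each of the 5 groups had 4 libraries, 20 in all. The deposited table gave FPKM values for 17310 gene symbols, and its sum per library lay between 306075 and 397357 FPKM, with 9397 to 10545 genes above 0. The read depth of the libraries is unknown, since the table held no counts. The time between treatment and lysis is not given in the sources used here. The design compared each treatment with PBS, the 3 TLR agonists with each other, and morphine with LPS. The questions, as the series describes them, were how microglia respond to opioid exposure and to TLR2 or TLR4 agonism.

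The agonists and the libraries themselves formed the main axes of variation. Across the 8858 tested genes, the first principal component held 43.5% of the variance and parted the TLR agonist libraries from the PBS and morphine libraries, and the second held 34.2% and divided the libraries within groups. After the group means were removed, 1 component held 63.2% of the remaining variance and separated 7 libraries from the other 13. The 7 were replicate 1 of every group with Morphine 2 and LPS 2, so that PBS, PAM3CSK4 and zymosan had 1 such library and morphine and LPS had 2. Rn18s, the 18S ribosomal RNA gene, was listed at 0 in 6 of the 7 libraries, at 6244 FPKM in the remaining one (LPS 1) and at 2658 FPKM or more in the other 13. The median FPKM of the tested genes was 5.64 to 8.16 in the 7 libraries and 8.12 to 10.9 in the 13. Between these sets 6170 genes differed, 1161 higher and 5009 lower in the smaller set (limma with terms for group and set), and after rescaling 5526, 2636 higher and 2890 lower. The sets were taken from these same values, so that differences between them were built in. Their p-values, here and below, show which genes and lists moved with the sets and do not test whether the sets exist. TLR receptors and adaptors (median log2 difference −0.73, adjusted p = 1.1e-08), homeostatic microglia genes (−0.47, adjusted p = 1.61e-09) and cell cycle genes (−0.55, adjusted p = 0.00199) were lower in the smaller set. The cell cycle difference was lost after rescaling (adjusted p = 0.209). Inflammatory cytokines and chemokines did not pass (−0.11, adjusted p = 0.33) and were higher in the smaller set after rescaling (0.25, adjusted p = 0.00618). Of the 27 tested lists, 25 differed between the sets. Counts of changed genes are given below also with a term for these sets and within the 13 libraries. The 7 held only 1 library each of PBS, PAM3CSK4 and zymosan. The term was taken from the spread that it removes, so calls with it, here and below, may be too many.

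**Figure D1:**
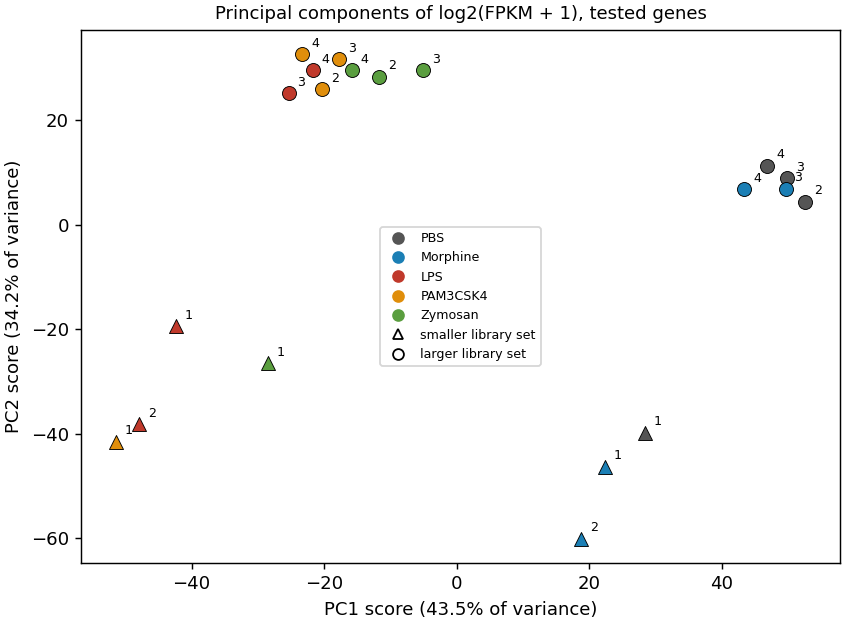
Scores of the 20 libraries on the first and second principal components of log2(FPKM + 1) over the tested genes, with 43.5% and 34.2% of the variance; colours give the group, symbols the library set and numbers the replicate. The PBS and morphine libraries lie at positive scores on the first component and the TLR agonist libraries at negative ones, and the 7 libraries of the smaller set all lie at negative scores on the second.

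Morphine left the levels of the inflammatory mediators within the spread between libraries. Il1b, which encodes the precursor of interleukin-1 beta, measured 235 ± 40.3 FPKM with PBS and 203 ± 47.5 with morphine (SD, n = 4 each, here and for every mean ± SD). Tnf, encoding tumour necrosis factor, measured 48.2 ± 10.2 and 54.9 ± 17.6 FPKM, and Ccl2, a monocyte-attracting chemokine, 1927 ± 662 and 2467 ± 960 FPKM. Nos2, the inducible nitric oxide synthase, stayed near 1 FPKM in both groups (0.895 ± 0.604 and 0.824 ± 0.579). Tlr4, the LPS receptor, measured 13.7 ± 4.62 FPKM with PBS and 9.64 ± 6.71 with morphine, and the fractalkine receptor gene Cx3cr1 68.7 ± 23.9 and 41.7 ± 12.9 FPKM. Of the 8858 genes, limma called 0 at an adjusted p under 0.05, with 104 at an unadjusted p under 0.05. The fit with a library-set term also called 0 genes, with 235 at an unadjusted p under 0.05, and 0 were called within the 13 libraries (240 unadjusted). The fold changes of the 8858 genes within the 7, with 1 PBS library, and within the 13 libraries correlated at −0.08, a correlation across genes, which are not independent replicates.

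The genes with the smallest unadjusted p that met the other conditions for naming were all lower with morphine, and none passed. Thtpa, encoding thiamine triphosphatase, measured 3.69 ± 2.28 FPKM against 7.05 ± 0.879 (log2 −0.96, SE 0.31, limma adjusted p = 0.897). Kdelr3, a receptor that returns proteins to the endoplasmic reticulum, differed by −0.62, Fam118b by −0.55, Isy1, a splicing factor, by −0.59 and Rab1b, a GTPase of transport to the Golgi, by −0.37. The morphine and PBS libraries did not overlap for 92 genes, or 1.04% of those tested, where chance gives 2.86%. Of the 27 gene lists tested, 0 were called with morphine. The lowest adjusted p of a list was 0.666, for several lists including homeostatic microglia genes (22 tested, median −0.33) and TLR receptors and adaptors (21 tested, median −0.31). Inflammatory cytokines and chemokines (28 tested, median 0.10) had an adjusted p of 0.727 in the rotation test; a test against all other genes with a preset correlation called them higher (camera, adjusted p = 0.000332), and the call was lost with an adjusted p = 0.729 with an estimated correlation.

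Opioid receptor genes were close to or at 0 in the table. Oprm1, Oprk1 and Oprl1, which encode the mu, kappa and nociceptin opioid receptors, were listed at 0 in all 20 libraries. Oprd1, the delta receptor gene, was listed at 0 in 19 libraries and at 0.113 FPKM in PBS 3. Since genes used by every cell, such as Creb3 in 5 libraries and Psma3 in 1, were also listed at 0, a listed 0 does not establish absence of the transcript. Ogfr, the opioid growth factor receptor gene, measured 28.2 ± 5.4 FPKM with PBS and 25.0 ± 2.04 with morphine, which did not pass. Over all tested genes, the 95% interval of the morphine change had a median half-width of 0.53 on the log2 scale, and 76.2% of the intervals lay within 1 log2 unit of 0, against 97.1% with the library-set term. For Il1b the interval ran from −0.67 to 0.22, for Tnf from −0.35 to 0.66, for Il6 from −0.46 to 0.68 and for Cxcl10, an interferon-induced chemokine, from −0.62 to 0.68. For Tlr4 it ran from −1.71 to 0.44 without the term and from −0.70 to 0.13 with it. Ptgs2, the inducible cyclooxygenase gene, had a wide interval, −1.74 to 1.37.

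LPS raised cytokine and chemokine genes and Nos2 by large factors and lowered the microglial genes Cx3cr1 and Gpr34 and cell cycle genes. Il1b rose to 10770 ± 2020 FPKM from 235 ± 40.3 with PBS (log2 fold change 5.51, SE 0.21, limma adjusted p = 1.61e-12), on the log2(FPKM + 1) scale, which understates changes of low genes. Nos2 rose to 370 ± 222 FPKM (log2 7.45), Lcn2, an iron-binding acute-phase protein gene, from 3.19 ± 1.01 to 815 ± 185 FPKM (log2 7.61), and Cxcl1, a neutrophil chemokine, from 22.0 ± 10.9 to 2134 ± 253 FPKM (log2 6.66). Cx3cr1 fell to 2.33 ± 1.75 FPKM (log2 −4.50), Gpr34, a lysophosphatidylserine receptor of microglia, from 30.3 ± 8.97 to 0.954 ± 0.539 FPKM (log2 −4.00), and Cdk1, the kinase that drives mitosis, from 68.1 ± 11 to 4.93 ± 1.86 FPKM (log2 −3.59). Csf3, the granulocyte colony-stimulating factor gene, was listed at 0 in 2 PBS libraries and at 1.86 and 0.82 FPKM in the others, and at 227 to 313 FPKM with LPS. Csf2, Cxcl3, Cd69, Mmp13, F3 and Il1a completed the 10 largest increases. Tf, the transferrin gene (67.5 ± 15.9 to 3.22 ± 1.09 FPKM), Lpl, lipoprotein lipase (526 ± 233 to 33.5 ± 18.8 FPKM), Rrm2, Plk1, Alox5ap, Spc25 and Gna15 completed the 10 largest decreases. In all, 2866 genes were called, 445 higher and 2421 lower, of which 1328 changed at least 2-fold (248 higher, 1080 lower). The set term gave 4458 calls and included all 2866, and 4202 genes were called within the 13 libraries. The median fold change of all genes was −0.37, and after median-ratio rescaling of the libraries 2287 genes were called, 1087 higher and 1200 lower, so that the share called higher was 47.5% in place of 15.5%.

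PAM3CSK4 raised cytokine and chemokine genes and Nos2 and lowered the microglial genes Cx3cr1 and Gpr34. Nos2 rose to 368 ± 171 FPKM (log2 7.48, SE 0.51, limma adjusted p = 4.31e-09), Cxcl1 to 3465 ± 457 FPKM (log2 7.36), Lcn2 to 538 ± 76.2 FPKM (log2 7.03) and Il1b to 10950 ± 2530 FPKM (log2 5.52). Cx3cr1 was listed at 0 in 1 library and at 2.24 to 5.22 FPKM in the others (log2 −4.46), Tf fell to 3.56 ± 1.43 FPKM (log2 −3.95) and Gpr34 to 1.27 ± 0.723 FPKM (log2 −3.80). Csf3, Csf2, Mmp13, Cd69, F3, which encodes the coagulation initiator tissue factor, Cxcl3 and Il1a were the other large increases. Alox5ap, needed for leukotriene synthesis (86.5 ± 15.3 to 7.02 ± 2.60 FPKM), Pld4, Spc25, Cdk1, Plk1, Dut and Fam64a were the other large decreases. The fit called 2496 genes, 498 higher and 1998 lower, with 1196 changed at least 2-fold, and the set term 4513 genes, which included all 2496. Within the 13 libraries 4279 genes were called. The median fold change was −0.27, and rescaling gave 2254 calls, 1062 higher and 1192 lower (47.1% higher in place of 20%).

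Zymosan raised cytokine genes and lowered microglial genes. Il1b rose to 10010 ± 1820 FPKM (log2 5.40, SE 0.21, limma adjusted p = 2.3e-12), Nos2 to 275 ± 141 FPKM (log2 7.04), Cxcl1 to 2137 ± 308 FPKM (log2 6.66) and Lcn2 to 279 ± 36.7 FPKM (log2 6.08). Cx3cr1 fell to 4.64 ± 2.51 FPKM (log2 −3.67), Tf to 5.83 ± 1.41 FPKM (log2 −3.32), Gpr34 to 3.20 ± 1.62 FPKM (log2 −2.94) and Gpr183, an oxysterol receptor, from 50.1 ± 3.35 to 6.90 ± 0.955 FPKM (log2 −2.70). Fabp3, a fatty acid binding protein gene, was listed at 5.88 to 8.83 FPKM in PBS and at 0 in all 12 TLR agonist libraries, and also at 0 in Morphine 3. Csf3, F3, Cxcl3, Csf2, Mmp13, Il1a and Cxcl2 completed the 10 largest increases, and Alox5ap, Pld4, Dhrs9, Muc20 and Spc25 the 10 largest decreases. The fit called 1670 genes, 413 higher and 1257 lower, with 800 changed at least 2-fold, the set term 3366 genes, which included all 1670, and the fit with the replicate number as a block 2619. Within the 13 libraries 3533 genes were called. The median fold change was −0.18, and rescaling gave 1553 calls, 733 higher and 820 lower (47.2% higher in place of 24.7%).

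**Figure D2:**
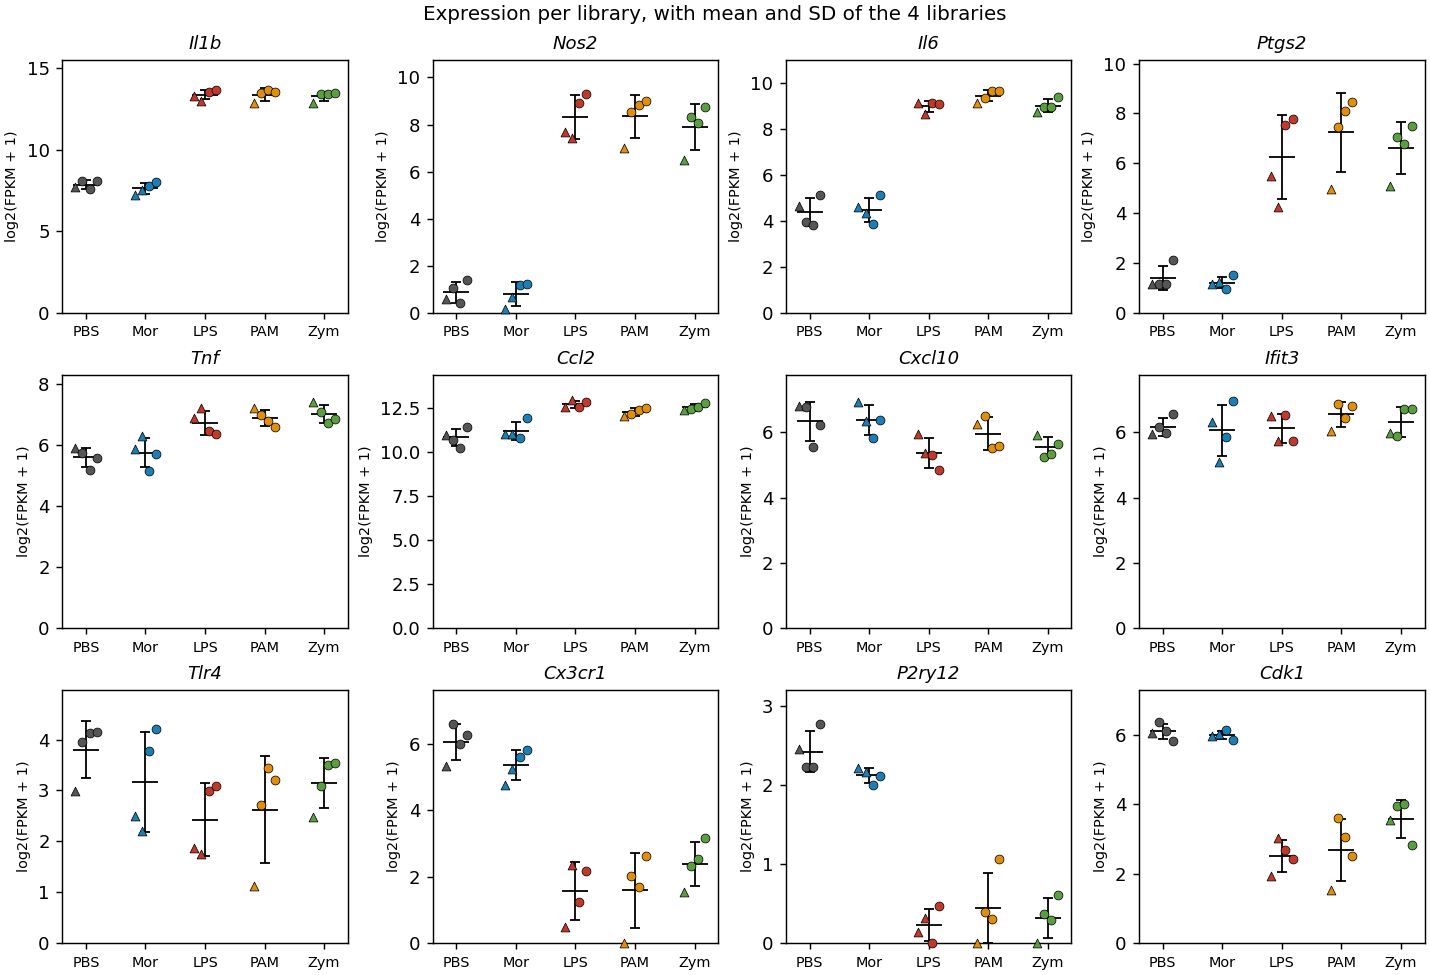
Expression of 12 genes in each library as log2(FPKM + 1), with the mean and SD of the 4 libraries of each group; triangles mark libraries of the smaller set. Il1b, Nos2, Il6 and Ptgs2 lie higher in the 3 TLR agonist groups than in PBS and morphine, and Cx3cr1 and Cdk1 lie lower.

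Inflammatory cytokines and chemokines rose as a list with each TLR agonist. Of 28 measured members, 20 rose and 2 fell with LPS, 20 and 1 with PAM3CSK4, and 21 and 1 with zymosan. Adjusted over the list alone, 22 rose and 2 fell, 22 and 1, and 21 and 2. After rescaling 0 members fell with any of the 3. The list test gave adjusted p values of 6.69e-11, 3.61e-11 and 5.45e-11, and an estimated correlation kept the calls (adjusted p = 0.000293, 0.000433 and 0.000202). Il6, an acute-phase cytokine, rose from 21.2 ± 9.55 FPKM to 513 ± 78.0 with LPS, 703 ± 119 with PAM3CSK4 and 521 ± 109 with zymosan. Tnf rose less, to 108 ± 31.2, 120 ± 22.0 and 131 ± 29.3 FPKM (log2 1.13, 1.30 and 1.42), and Ccl2 rose to 6859 ± 920, 5052 ± 721 and 6055 ± 776 FPKM. Cxcl10 was among the members that fell with LPS, to 42.0 ± 14.2 from 85.3 ± 31.5 FPKM (log2 −0.98, SE 0.31, limma adjusted p = 0.022), and this call was lost after rescaling (log2 −0.55, SE 0.40, adjusted p = 0.354).

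Genes of the NF-kB pathway and its feedback also rose, with 20 of 30 higher after LPS, 23 after PAM3CSK4 and 22 after zymosan, and 0 lower. Adjusted over the list alone the counts were 22, 24 and 24. The calls were kept with an estimated correlation (adjusted p = 0.0115, 0.0119 and 0.0086). Sod2, the mitochondrial superoxide dismutase, rose from 271 ± 33.5 to 1290 ± 74.5, 1292 ± 158 and 1272 ± 137 FPKM. Nfkbiz, a nuclear regulator of NF-kB target genes, rose by 2.39, 2.89 and 2.64 and Birc3, an inhibitor of apoptosis, by 2.58, 2.82 and 2.42 on the log2 scale. The list was lower in the smaller library set (median −0.58, adjusted p = 2.68e-07). Immediate early genes (24 measured) had 9 higher and 2 lower members with LPS, 11 and 1 with PAM3CSK4 and 10 and 1 with zymosan (9 and 2, 11 and 1, and 11 and 1 adjusted over the list alone), led by Ier3 and Zfp36, an mRNA-destabilising protein. These calls held with an estimated correlation (adjusted p = 0.0107, 0.00819 and 0.0086). Glucocorticoid target genes (14 measured) had 7 higher members with each TLR agonist, and 1 lower with LPS, with the same counts adjusted over the list alone and an adjusted p = 0.00244, 0.00414 and 0.00265 with an estimated correlation. The members with the largest changes were Lcn2 and the metallothioneins Mt2A (log2 5.73, 4.87 and 4.24) and Mt1a (3.19, 2.16 and 2.08), metal-binding proteins also induced by inflammation. Immediate early and glucocorticoid target genes were lower in the smaller library set (median −0.22 and −0.26, adjusted p = 0.00652 and 5.17e-05) but higher there after rescaling (0.11 and 0.14, adjusted p = 3.41e-05 and 0.00157).

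Prostaglandin and nitric oxide synthesis genes moved both ways. Of 22 members, 11 rose and 4 fell with LPS, 10 and 5 with PAM3CSK4, and 9 and 2 with zymosan (11 and 6, 10 and 5, and 10 and 3 adjusted over the list alone). The list was called higher with each (adjusted p = 0.00547, 0.0119 and 0.00528), and these calls were lost with an adjusted p = 0.157, 0.176 and 0.158 with an estimated correlation. The list was lower in the smaller library set (median −0.54, adjusted p = 6.86e-06), which was lost after rescaling (adjusted p = 0.141). Ptgs2 rose from 1.76 ± 1.07 to 116 ± 99.9, 207 ± 139 and 114 ± 61.5 FPKM (log2 4.87, 5.85 and 5.22). Slc7a2, an arginine transporter, rose by 5.16, 5.06 and 4.85 and IRG1, which makes itaconate, by 4.16, 3.43 and 3.77, whereas Alox5ap fell by 3.47, 3.49 and 2.74 on the log2 scale.

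Homeostatic microglia genes fell, with 15 of 22 lower after LPS, 15 after PAM3CSK4 and 13 after zymosan, and 0 higher. Adjusted over the list alone 17, 16 and 14 fell, and after rescaling 14, 14 and 13. The list test was called with each (adjusted p = 9.7e-07, 9.82e-07 and 1.41e-05), and these calls were lost with an adjusted p = 0.163, 0.12 and 0.127 with an estimated correlation. This list was also lower in the smaller library set. Csf1r, the receptor for the survival factors of microglia, fell from 512 ± 73.2 FPKM to 106 ± 26.8, 92.6 ± 21.6 and 144 ± 15.1. Tmem119, a microglial marker, fell from 19.1 ± 3.45 to 6.53 ± 3.15, 6.97 ± 4.57 and 8.09 ± 3.21 FPKM. P2ry12, a purinergic receptor of resting microglia, was listed at 3.70 to 5.84 FPKM with PBS and at 0 to 0.383 with LPS, 0 to 1.08 with PAM3CSK4 and 0 to 0.527 with zymosan (log2 −2.20, −1.98 and −2.11). Trem2 fell by 2.37, 2.46 and 1.74 on the log2 scale.

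Every measured cell cycle gene fell with every TLR agonist, 29 of 29, over all genes, over the list alone and after rescaling. The median log2 changes were −2.67 with LPS, −2.53 with PAM3CSK4 and −2.01 with zymosan. The list was called by fry (adjusted p = 4.56e-08, 2.37e-07 and 2.98e-06). Camera, which compares it with other genes, did not call it with an estimated correlation (adjusted p = 0.0716, 0.0787 and 0.0732). That test asks another question and leaves the fall of the 29 members as it was. The list was also lower in the smaller library set. Cdk1 fell to 6.28 ± 3.95 FPKM with PAM3CSK4 and 11.6 ± 4.18 with zymosan, and Rrm2, a subunit of ribonucleotide reductase, from 109 ± 16.9 to 8.60 ± 3.43, 15.1 ± 3.91 and 24.6 ± 6.29 FPKM.

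Antigen processing and MHC genes had 8 of 19 members lower with LPS, 9 with PAM3CSK4 and 8 with zymosan, and 1, 1 and 0 higher (8, 10 and 9 lower and 1, 1 and 0 higher adjusted over the list alone). The list was called lower with each (adjusted p = 2.4e-07, 2.43e-07 and 1.03e-06), and these calls were lost with an adjusted p = 0.266, 0.176 and 0.104 with an estimated correlation. RT1-DMa and RT1-DMb, which load peptides onto class II molecules, fell, RT1-DMa by 2.97, 2.89 and 2.50 and RT1-DMb by 2.37, 2.66 and 2.47 on the log2 scale. Complement genes (14 measured) had 7, 7 and 5 lower and 1, 2 and 2 higher members (8, 8 and 8 lower and 1, 3 and 3 higher adjusted over the list alone). Their calls (adjusted p = 0.000178, 0.00142 and 0.00774) were lost with an adjusted p = 0.705, 0.7 and 0.768 with an estimated correlation. Complement genes were lower in the smaller library set (median −0.39, adjusted p = 1.69e-06), still called lower after rescaling (adjusted p = 0.0151) with a median of 0.005, and antigen processing genes did not differ there (median 0.05, adjusted p = 0.908) but were higher after rescaling (0.45, adjusted p = 3.41e-05). The C1q subunits C1qb and C1qc fell by 2.34 and 2.51 with LPS on the log2 scale, and the C3a receptor gene C3ar1 rose by 1.37, 1.37 and 1.61.

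Interferon-stimulated genes were not called as a list with any TLR agonist (adjusted p = 0.102, 0.305 and 0.25). Of 41 members, 3 rose and 14 fell with LPS, 4 and 12 with PAM3CSK4, and 3 and 9 with zymosan (3 and 14, 5 and 14, and 3 and 12 adjusted over the list alone). After rescaling the counts that fell were 8, 6 and 4. Cd274, encoding the checkpoint ligand PD-L1, rose by 1.98, 2.46 and 2.77 on the log2 scale, and Usp18, an inhibitor of interferon signalling, by 1.11, 1.23 and 1.29. Ifit2 fell with LPS by 1.91, and Ifit3 did not pass with any (71.9 ± 15.1 FPKM with PBS, 71.3 ± 21.8, 95.1 ± 23.8 and 81.8 ± 25.5 with the TLR agonists). The list was lower in the smaller library set (median −0.50, adjusted p = 0.00142), which was lost after rescaling (adjusted p = 0.238). TLR receptors and adaptors (21 measured) were not called either (adjusted p = 0.0527, 0.161 and 0.394), with 6, 4 and 3 members lower and 0, 1 and 1 higher (9, 4 and 3 lower and 0, 1 and 1 higher adjusted over the list alone). The set term called this list lower with each (adjusted p = 0.000433, 0.000475 and 0.0204) and the replicate block with PAM3CSK4 (adjusted p = 0.047), whereas the fit without either gave an adjusted p = 0.95, 0.938 and 0.991 with an estimated correlation. The block also called the list lower with LPS (adjusted p = 0.00578), where the numbers did not pair the libraries by the rule used. After rescaling it was not called (adjusted p = 0.244, 0.641 and 0.911) and the zymosan median of −0.16 turned to 0.04. The list was lower in the smaller library set. Tlr3, the receptor for double-stranded RNA, fell by 2.37, 1.97 and 1.88 on the log2 scale. Tlr4 fell to 4.86 ± 2.73 FPKM with LPS (log2 −1.38, SE 0.51, limma adjusted p = 0.0463), a call lost after rescaling (log2 −1.01, SE 0.41, adjusted p = 0.0738), and measured 6.22 ± 3.81 with PAM3CSK4 and 8.25 ± 2.84 with zymosan, which did not pass, although both were called lower with the set term (adjusted p = 6.51e-05 and 0.0128) and PAM3CSK4 with the replicate block (adjusted p = 0.00205). Tlr2 measured 136 ± 34.5 FPKM with PBS and 142 ± 63.1, 144 ± 56.1 and 178 ± 52.3 with the TLR agonists and did not pass, although within the 13 libraries it rose with LPS (log2 0.36, adjusted p = 0.021) and the set term called it higher with zymosan (log2 0.37, adjusted p = 0.0138). The LPS co-receptor gene Cd14 fell with PAM3CSK4 (1128 ± 247 to 696 ± 180 FPKM, log2 −0.71, SE 0.23, adjusted p = 0.03), a call lost after rescaling (log2 −0.39, SE 0.22, adjusted p = 0.215), and did not pass with LPS (754 ± 219 FPKM; adjusted p = 0.0448 with the set term) or zymosan (968 ± 177 FPKM).

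**Figure D3:**
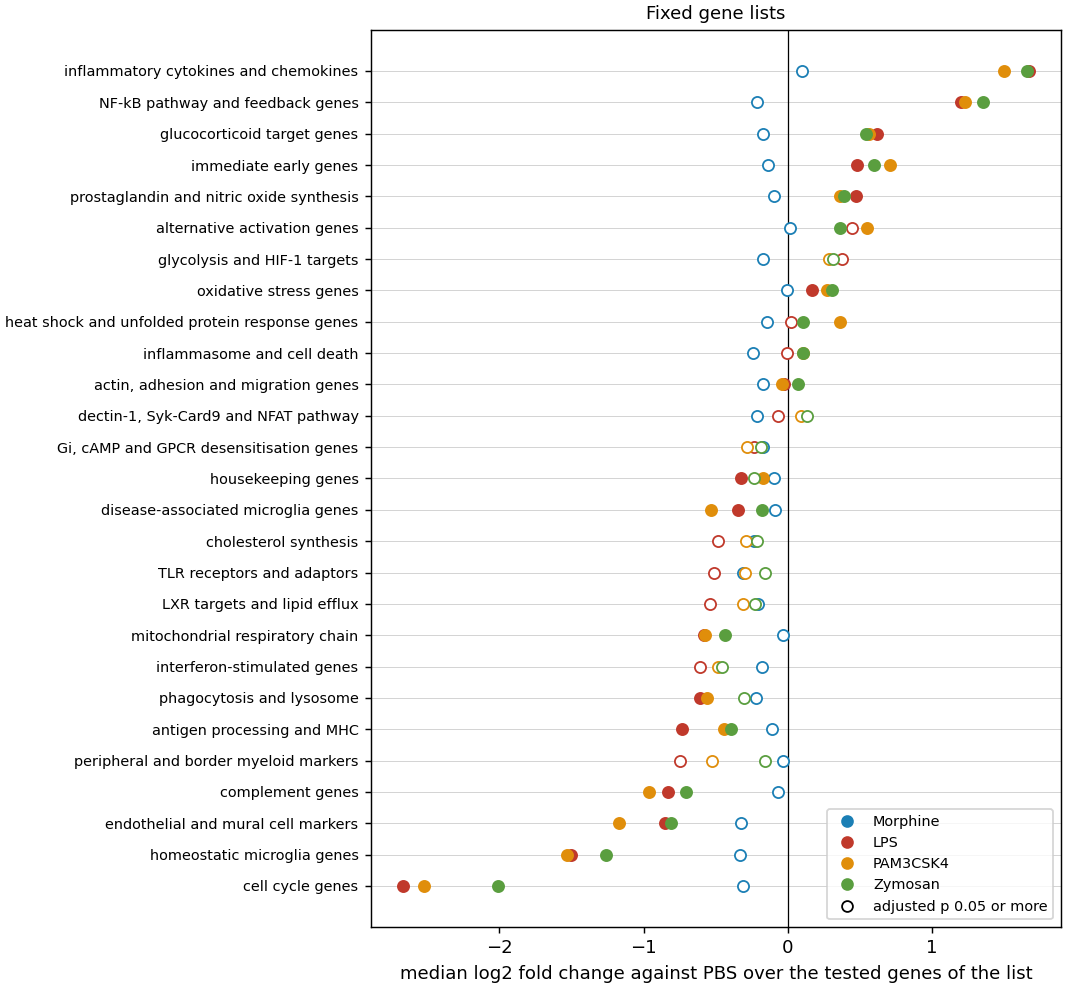
Median log2 fold change against PBS over the tested genes of each of the 27 fixed lists, for morphine and the 3 TLR agonists; filled points passed the list test at an adjusted p under 0.05 and open points did not. No point of morphine is filled, and the cell cycle list lies lowest with LPS at −2.67; after rescaling the medians of 12 lists with morphine, 6 with LPS, 3 with PAM3CSK4 and 2 with zymosan change sign.

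The fold changes of the TLR agonists ran in parallel across genes. Across the 8858 genes the fold changes against PBS of LPS and PAM3CSK4 correlated at 0.941. Those of LPS and zymosan correlated at 0.927 and those of PAM3CSK4 and zymosan at 0.962. Simulated unchanged groups with shared controls gave means of 0.475, 0.487 and 0.449 in 100 simulations. Their highest values were 0.933, 0.908 and 0.946, close to the observed values. Their controls were drawn from all 20 libraries after the group means were removed. They could thus hold more or fewer libraries of the smaller set than PBS did. The simulated values, here and for morphine below, are therefore not those of the real PBS libraries. The covariances were 0.544, 0.468 and 0.478 against simulated means of 0.0461, 0.0464 and 0.0485 and highest simulated values of 0.217, 0.211 and 0.235. With the PBS libraries split between the comparisons, the correlations were still 0.77 to 0.897, 0.724 to 0.882 and 0.81 to 0.869. Higher with both LPS and PAM3CSK4 were 379 genes, Il1b and Nos2 among them, where independent lists would share 25, and lower with both were 1763 where independent lists would share 546. Independent lists leave out the shared PBS libraries. The simulated unchanged groups, which shared their controls, had 0 called genes in common in each of the 100 simulations, in either direction. Unchanged groups leave hardly any gene to call, so this 0 was set beforehand. How much the shared PBS libraries add to the overlap was not measured. With all 3 TLR agonists 327 genes were higher and 1179 lower (633 and 731 after rescaling), and 0 genes were called in opposite directions. For morphine and LPS the correlation was 0.243 against a simulated mean of 0.446, and the covariance 0.0434 against 0.0421. For morphine with PAM3CSK4 and with zymosan the correlations were 0.13 and 0.098, against simulated means of 0.475 and 0.436.

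**Figure D4:**
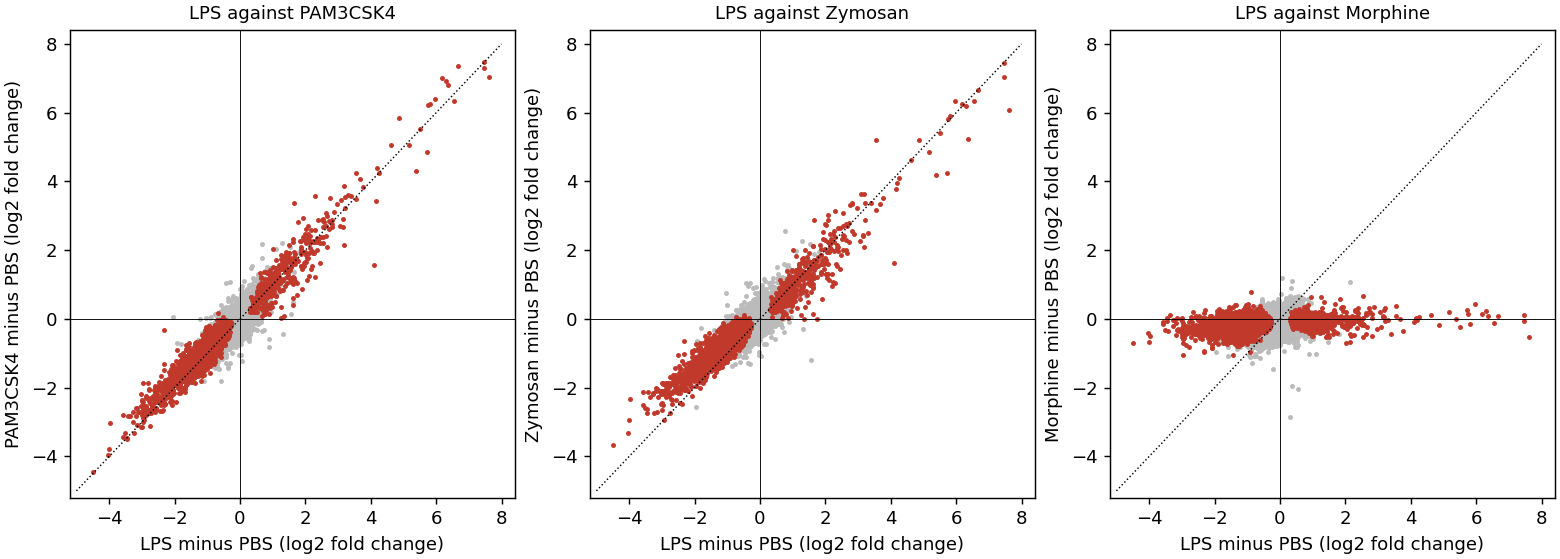
Log2 fold changes against PBS of all tested genes, with LPS on the horizontal axis and PAM3CSK4, zymosan or morphine on the vertical axis; red points were called with LPS and the dotted line marks equal change. The PAM3CSK4 and zymosan changes lie along the dotted line (correlations of 0.941 and 0.927 across genes) and the morphine changes do not (0.243).

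Directly compared, PAM3CSK4 and LPS differed in 3 genes. Il10, an anti-inflammatory cytokine, was higher with PAM3CSK4, at 15.3 ± 4.33 against 3.91 ± 1.00 FPKM (log2 1.71, SE 0.29, limma adjusted p = 0.0364), with 4 of 4 libraries above all LPS libraries, and the call was lost after rescaling (log2 1.63, SE 0.28, adjusted p = 0.0501). Ccl5, a chemokine for T cells and monocytes, was lower, at 5.08 ± 2.67 against 32.4 ± 8.21 FPKM (log2 −2.54), as was the calmodulin gene Calm3, at 40.1 ± 4.23 against 68.7 ± 5.21 FPKM (log2 −0.77, SE 0.13), lost after rescaling (log2 −0.89, SE 0.19, adjusted p = 0.185). Among genes that met the other conditions for naming, Crip2 (log2 −1.01, adjusted p = 0.24) and Calm2 (log2 −0.43, adjusted p = 0.292) had the next smallest p. Neither passed, although both did with the set term (adjusted p = 0.00864 and 0.0176). At an unadjusted p under 0.05 there were 343 genes, and 0 of the 27 lists were called. Leaving out single libraries gave 0 genes without any of the 4 LPS libraries or PAM3CSK4 1 or 2, 1 gene without PAM3CSK4 3 and 2 without PAM3CSK4 4. The set term called 11 genes, and 1 gene was called within the 13 libraries. With the replicate number as a block 7 were called, although the numbers did not pair these libraries by the rule used.

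Zymosan and LPS differed in 8 genes. Higher with zymosan were Rrm2 (24.6 ± 6.29 against 8.60 ± 3.43 FPKM, log2 1.46, SE 0.27, limma adjusted p = 0.0365), Nradd, a death-domain receptor homologue (10.8 ± 1.58 against 4.89 ± 0.523 FPKM), and Dnase2, the lysosomal DNase (68.2 ± 5.96 against 41.1 ± 3.81 FPKM). Lower were Lcn2 (279 ± 36.7 against 815 ± 185 FPKM, log2 −1.53), Ccl5 (5.08 ± 1.89 against 32.4 ± 8.21 FPKM, log2 −2.48), Crip2 (log2 −1.47), Calm2 and Stap2, an adaptor protein (1.14 ± 0.536 against 4.04 ± 1.23 FPKM, log2 −1.23), which lay under the level required for naming and was chosen after its values were seen. The calls of Nradd, Dnase2 and Calm2 (log2 1.00, 0.72 and −0.56, SE 0.19, 0.11 and 0.09) were lost after rescaling (log2 0.80, 0.49 and −0.78, SE 0.17, 0.16 and 0.16, adjusted p = 0.0662, 0.385 and 0.0641). The set term called 96 genes, 81 higher and 15 lower, and the 13 libraries 16 genes. With the replicate number as a block 152 were called, 132 higher and 20 lower, although the numbers did not pair these libraries by the rule used. Leaving out LPS 1 or LPS 3 gave 3 genes, Zymosan 2 or Zymosan 3 gave 2, Zymosan 1 gave 4 and LPS 2 gave 5. Cell cycle genes were higher with zymosan as a list (29 measured, median 0.88, adjusted p = 0.0264), with 1 member called over all genes and 21 adjusted over the list alone, and the call was lost with an adjusted p = 0.318 with an estimated correlation. After rescaling it was kept (adjusted p = 0.03), phagocytosis and lysosome genes were also called higher (adjusted p = 0.0321), and glycolysis and HIF-1 targets (adjusted p = 0.03) and glucocorticoid target genes (adjusted p = 0.00246, median 0.03 before and −0.18 after) were called lower. These 3 had an adjusted p = 0.686, 0.686 and 0.29 with an estimated correlation without rescaling. No list was called without LPS 2, LPS 4, Zymosan 1 or Zymosan 3 or with only the 2 groups in the fit, and 1 was called without LPS 1. Mitochondrial respiratory chain genes (22 measured, median 0.22) and disease-associated microglia genes (23 measured, median 0.24) had the same adjusted p of 0.0264, lost with an adjusted p = 0.686 for each with an estimated correlation. Both were also lost after rescaling (adjusted p = 0.842 and 0.19), where the median of the mitochondrial list changed sign to −0.003 and that of the other list was 0.03.

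For zymosan against PAM3CSK4, 0 genes passed in limma, with 299 at an unadjusted p under 0.05. The set term called 8 genes, the replicate number as a block 8, 5 higher and 3 lower with zymosan, and 1 gene was called within the 13 libraries. Among genes that met the other conditions for naming, the smallest p were those of Cd69, an activation marker (52.0 ± 22.7 with zymosan against 150 ± 33.1 FPKM with PAM3CSK4, limma adjusted p = 0.26), Cd68, a lysosomal glycoprotein gene (235 ± 31.2 against 157 ± 18.1 FPKM), Ccnd1, Batf and Lcn2. None of them passed. With the set term Cd69, Cd68, Ccnd1 and Batf did (adjusted p = 0.037, 0.0191, 0.037 and 0.037), and with the block Cd69, Cd68 and Batf did (adjusted p = 0.0265, 0.0429 and 0.0429). Of the 27 lists, 0 were called, with a lowest adjusted p of 0.182. With the block disease-associated microglia genes were called higher with zymosan (median 0.29, adjusted p = 0.0146, and 0.0347 with the set term), with an adjusted p = 0.243 with an estimated correlation without either and 0.114 after rescaling. Further lists were called with the set term and are counted below. The intervals of the difference were −0.56 to 0.32 for Il1b, −1.01 to 0.13 for Il6 and −0.39 to 0.62 for Tnf.

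Morphine and LPS libraries, compared directly, differed in 2256 genes, 1744 higher and 512 lower with morphine (2207 after rescaling, 1139 higher and 1068 lower, or 51.6% higher in place of 77.3%). Il1b was lower with morphine, 203 ± 47.5 against 10770 ± 2020 FPKM (log2 −5.73, SE 0.21, limma adjusted p = 7.77e-13), as were Lcn2 (1.96 ± 0.833 against 815 ± 185 FPKM, log2 −8.12), Nos2 (log2 −7.52), Cxcl1 (log2 −6.58), Il6 (log2 −4.51), Il1a, Csf3, Cxcl3, Cd69, Mmp13 and Csf2. Cx3cr1 was higher, 41.7 ± 12.9 against 2.33 ± 1.75 FPKM (log2 3.81), as were Tf (log2 3.61), Lpl (log2 3.49), Alox5ap, Gpr34 and the cell cycle genes Cdk1 (63.1 ± 5.46 against 4.93 ± 1.86 FPKM), Ube2c, Rrm2, Spc25 and Ccna2. The set term called 4111 genes, the 13 libraries 3495 and the 7 libraries, with 2 of each group, 801.

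Few markers of other cell types passed the filter on low values. Gfap and Aqp4, astrocyte genes, and Cd3e, a T cell gene, were listed at 0 in all 20 libraries, which, as for the opioid receptor genes, does not establish absence. Under the filter, 2 of 12 astrocyte markers, 3 of 13 oligodendrocyte lineage markers, 2 of 13 neuron markers, 4 of 16 lymphocyte markers and 0 of 10 fibroblast and 0 of 8 red cell genes were tested, too few for a list test. Tubb3, a neuronal tubulin, rose with LPS from 3.54 ± 1.53 to 11.3 ± 4.88 FPKM (log2 1.42, limma adjusted p = 0.0134), and Il7r, the interleukin-7 receptor gene, from 38.5 ± 10.5 to 93.8 ± 20.3 FPKM (log2 1.27). Cnp, a myelin enzyme gene, fell from 23.7 ± 5.49 to 10.8 ± 4.07 FPKM (log2 −1.10). Cspg4, which encodes the NG2 proteoglycan of oligodendrocyte precursors, fell by 1.92 on the log2 scale. Endothelial and mural cell markers (5 tested) had 3, 4 and 2 members lower with LPS, PAM3CSK4 and zymosan and 0 higher (0 higher and 3 lower, 1 and 4, and 1 and 2 adjusted over the list alone). Their list calls (adjusted p = 0.00214, 0.0017 and 0.0145) were lost with an adjusted p = 0.705, 0.605 and 0.722 with an estimated correlation, and the list was also lower in the smaller library set (median −0.77, adjusted p = 1.07e-07). Cdh5, the endothelial cadherin, fell by 1.73, 1.55 and 1.54 on the log2 scale. Peripheral and border myeloid markers (6 tested) were not called (adjusted p = 0.682, 0.471 and 0.902), but were called lower with the set term (adjusted p = 0.00287, 9.35e-05 and 0.00328) and with PAM3CSK4 with the replicate block (adjusted p = 0.00851). LPS libraries, whose numbers did not pair with those of PBS by the rule used, also gave a lower call with the block (adjusted p = 0.014). Without these terms the markers had an adjusted p = 0.705, 0.881 and 0.84 with an estimated correlation. Their members were 2 higher and 3 lower with LPS, 2 and 1 with PAM3CSK4 and 2 and 1 with zymosan (2 and 3, 2 and 3, and 2 and 2 adjusted over the list alone). Pf4, a platelet chemokine also made by macrophages, rose by 2.67, 2.09 and 1.93, and Lyve1, a hyaluronan receptor, fell by 1.70, 2.10 and 1.65.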

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

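The gap of each library to the other 3 of its group was tested by a planned rule, and only the library sets named beside the values were found after the data had been seen. Of 173 gene and group values examined, 14 had a library far from the other 3, where chance gives about 1 in 20, and 7 of the 14 lay in the smaller library set. Il1b was 7300.81 FPKM in Zymosan 1 against 10720 to 11199 in the other libraries of its group. Tlr2 was 100.004 FPKM in Zymosan 1 against 199 to 211. Il6 was 395.966 FPKM in LPS 2 against 544 to 560. Il1a was 1942.68 FPKM in PAM3CSK4 1 against 3821 to 4126. Csf1r was 60.447 FPKM in PAM3CSK4 1 against 101 to 107. Nradd was 5.569 FPKM in PAM3CSK4 1 against 8.81 to 8.97. Kdelr3 was 6.602 FPKM in Morphine 2 against 13.2 to 14.1. In the larger set, Ptgs2 was 3.368 FPKM in PBS 4 against 1.21 to 1.23. Ccl2 was 3893.45 FPKM in Morphine 4 against 1804 to 2093. Cd14 was 1082.52 FPKM in LPS 4 against 640 to 651, and Tubb3 18.576 against 8.63 to 9.12 in the same library. Il10 was 1.17 FPKM in PBS 3 against 0.307 to 0.392. Crip2 was 5.923 FPKM in Zymosan 3 against 8.44 to 8.74, and Dnase2 77.102 against 64.5 to 65.6.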

How the results depend on the processing

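The library-set term, the fits within the 13 and within the 7 libraries and the exact zeros treated as missing were chosen after the data had been seen. Counts within 1.5 times those of the report are left out below, and the cause of each change was not tested, except that the fits within a set held fewer libraries. In the 7 libraries, PBS, PAM3CSK4 and zymosan had 1 library each, assumed to vary like the 2 each of morphine and LPS that gave the whole spread (2 residual degrees of freedom), so their counts there support no result. For LPS, PAM3CSK4 and zymosan against PBS, library quality weights called 4641, 4297 and 3497 genes, and the library-set term 4458, 4513 and 3366. With the replicate number as a block, LPS called 4340 and zymosan 2619, a comparison with paired numbers. The 13 libraries gave 4279 genes with PAM3CSK4 and 3533 with zymosan, and the 7 libraries 442, 332 and 48. For morphine against LPS, quality weights gave 3582, the set term 4111, the 13 libraries 3495 and the 7 libraries 801.

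For PAM3CSK4 against LPS (3 in the report), the genes called were 0 with a pseudocount of 0.1 FPKM, 0 with no filter, 0 with only the 2 groups compared, 37 with quality weights, 7 with the replicate block, 11 with the set term, and 1 in the 13 and 1 in the 7 libraries. For zymosan against LPS (8), they were 183 with quality weights, 152 with the replicate block, 96 with the set term, 16 in the 13 libraries, 0 in the 7 and 3 with only the 2 groups compared. For zymosan against PAM3CSK4 (0), they were 18 with quality weights, 8 with the replicate block, 8 with the set term, 1 in the 13 libraries, 1 in the 7 and 1 with no filter.

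The lists called with an estimated correlation were 4 each for LPS, PAM3CSK4 and zymosan against PBS and 0 for zymosan against LPS. With a preset correlation they were 1 for morphine, 4 for PAM3CSK4 against LPS, 5 for zymosan against LPS and 10 for zymosan against PAM3CSK4. The 7 libraries gave 3, 3 and 2 lists for the TLR agonists against PBS and 0 for zymosan against LPS. For zymosan against LPS (3), lists were 7 with the replicate block, 6 with the set term and 0 with only the 2 groups compared. Quality weights gave 1 list for PAM3CSK4 against LPS and 1 for zymosan against PAM3CSK4, where the replicate block gave 1, the set term 3 and the 13 libraries 1.

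Leaving out each library in turn gave 0 to 1 genes for morphine, 2235 to 2978 for LPS, 1922 to 2421 for PAM3CSK4, 1250 to 1549 for zymosan, 0 to 2 for PAM3CSK4 against LPS, 2 to 9 for zymosan against LPS, 0 for zymosan against PAM3CSK4 and 1913 to 2262 for morphine against LPS. The lists were 16 to 18, 19 to 20 and 15 to 17 for the TLR agonists and 0 to 3 for zymosan against LPS. Over 981 changes of named genes, 16926 of 17656 repeats left the call as it was, 663 lost it and 66 gained it. The sign changed in 1061 repeats called in neither fit and in 1 more, which gained a call: Tlr2 with LPS, −0.005 in the report, was 0.357 in the 13 libraries (adjusted p = 0.021). In the 4 comparisons with paired numbers, the replicate block ended no call. Besides those given beside the results, it called Calm2 with PAM3CSK4, Cnp, Cxcl10 and Thtpa with zymosan, Trem2 for zymosan against PAM3CSK4 and Tlr4, Cd14 and Cnp for morphine against LPS, and changed no other call of a gene or list in the text. In the other 4 comparisons only the pair with number 2, whose libraries lay in different library sets, failed the rule. The remaining pairs of the same number correlated at 0.437 to 0.762, so shared handling is not excluded there. Over all groups 19 of 20 libraries correlated best with a library of their own number, a hint from the data. Read depth is unknown, so its limit on low genes was not measured.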

Other observations

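The test of the library sets as the reason that no gene was called with morphine, and every fit with a library-set term, were chosen after the result was seen.

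The matrix gene Mmp13 was among the 10 largest increases with each TLR agonist. Of 26 actin, adhesion and migration genes, 8 rose with each TLR agonist and 4, 3 and 1 fell with LPS, PAM3CSK4 and zymosan (8 rose and 4, 4 and 2 fell adjusted over the list alone). The list was called higher (adjusted p = 0.0057, 0.0017 and 0.00112), a call lost with an adjusted p = 0.166, 0.176 and 0.138 with an estimated correlation, and its median of −0.03 with LPS and −0.04 with PAM3CSK4 turned positive after rescaling (0.41 and 0.28). Mmp13, a collagenase, rose by 6.30, 6.93 and 6.20 on the log2 scale and Mmp3, a stromelysin, by 4.27, 4.26 and 4.11. Alternative activation genes (10 measured) had 2, 2 and 3 higher and 1, 0 and 0 lower members (2, 3 and 4 higher and 1, 0 and 0 lower adjusted over the list alone), and were called higher with PAM3CSK4 and zymosan (adjusted p = 0.00341 and 0.00155), lost with an adjusted p = 0.12 and 0.0818 with an estimated correlation. With LPS they were not called (adjusted p = 0.0587, and 0.139 with an estimated correlation) but were called higher after rescaling (adjusted p = 0.000121) and with the set term (adjusted p = 0.000121). The replicate block called them higher with LPS too (adjusted p = 0.0272), where the numbers did not pair the libraries by the rule used. Arg1, an arginine-degrading enzyme, rose by 2.82, 2.67 and 3.37. Oxidative stress genes (19 measured) had 6, 5 and 6 higher and 3, 4 and 2 lower members (6, 6 and 6, and 3, 4 and 3 adjusted over the list alone), with calls (adjusted p = 0.00129, 0.00142 and 0.00168) lost with an adjusted p = 0.101, 0.12 and 0.127 with an estimated correlation. Slc7a11, a cystine transporter, rose by 1.88, 2.28 and 1.86. Heat shock and unfolded protein response genes (23 measured) had 5, 9 and 6 higher and 2, 1 and 1 lower members (6, 9 and 6, and 2, 1 and 1 adjusted over the list alone), called with PAM3CSK4 and zymosan (adjusted p = 0.00158 and 0.0309) and lost with an adjusted p = 0.12 and 0.201 with an estimated correlation. With LPS they were not called (adjusted p = 0.162, and 0.244 with an estimated correlation) but were called higher after rescaling (adjusted p = 1.24e-05, median 0.02 before and 0.45 after) and with the set term (adjusted p = 0.0463). Hspb1, a small heat shock protein, rose by 2.86, 3.12 and 2.46. Inflammasome and cell death genes (18 measured) had 4 higher members with each and 5, 3 and 3 lower (4 higher and 5, 3 and 4 lower adjusted over the list alone), called higher with PAM3CSK4 and zymosan (adjusted p = 0.0109 and 0.00669) and lost with an adjusted p = 0.176 and 0.208 with an estimated correlation. With LPS they were not called (adjusted p = 0.126, and 0.251 with an estimated correlation) but were called higher after rescaling (adjusted p = 6.5e-10), where the median of −0.007 turned to 0.35, and with the set term (adjusted p = 9.26e-06). A higher call with LPS also came from the replicate block (adjusted p = 0.0234), without paired numbers. Pycard, the inflammasome adaptor, fell by 2.40, 2.38 and 1.98. Glycolysis and HIF-1 targets (22 measured) had 8, 6 and 6 higher and 1 lower member each (11, 6 and 6, and 2, 1 and 1 adjusted over the list alone), not called (adjusted p = 0.0547, 0.15 and 0.16) but called higher after rescaling (adjusted p = 1.57e-07, 5.44e-06 and 3.38e-05), with the set term (0.000196, 0.00848 and 0.0059) and, for PAM3CSK4 and zymosan, with the replicate block (0.0445 and 0.047), with an adjusted p = 0.242, 0.377 and 0.337 with an estimated correlation without these. The block also called this list higher with LPS (adjusted p = 0.0109), without paired numbers. Egln3, an oxygen-sensing prolyl hydroxylase, rose by 2.24, 1.92 and 1.07.

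Several lysosomal, lipid and mitochondrial lists held more members that fell than rose. Disease-associated microglia genes (23 measured) had 10, 11 and 7 lower and 3 higher members with each (11, 11 and 8 lower and 3 higher adjusted over the list alone), called lower (adjusted p = 3.83e-05, 8.89e-05 and 0.0278) and lost with an adjusted p = 0.786, 0.605 and 0.991 with an estimated correlation, and the median of −0.34 with LPS and −0.18 with zymosan turned to 0.09 and 0.03 after rescaling, where the zymosan call was lost (adjusted p = 0.637). This list and housekeeping genes were lower in the smaller library set (median −0.14 and −0.31, adjusted p = 0.00587 and 0.000136) but higher there after rescaling (0.27 and 0.09, adjusted p = 0.000505 and 9e-07). Igf1, a growth factor, fell by 2.68, 2.49 and 2.16 on the log2 scale. Phagocytosis and lysosome genes (35 measured) had 15, 12 and 7 lower and 3 higher members with each (18, 14 and 8 lower and 3 higher adjusted over the list alone), called lower with LPS and PAM3CSK4 (adjusted p = 0.00532 and 0.0154) and lost with an adjusted p = 0.786 and 0.881 with an estimated correlation. The PAM3CSK4 call was also lost after rescaling (adjusted p = 0.0761), with zymosan the list was called lower with the set term (adjusted p = 0.0359, and 0.991 with an estimated correlation without it), and the list was lower in the smaller library set (median −0.42, adjusted p = 5.82e-07). Gusb, a lysosomal glucuronidase, fell by 2.12, 1.58 and 1.57, and Fcgr2b, an inhibitory antibody receptor, rose by 1.12, 1.29 and 1.83. Mitochondrial respiratory chain genes (22 measured) had 13, 11 and 5 lower and 0 higher (14, 12 and 5 lower adjusted over the list alone), with calls (adjusted p = 1.15e-07, 4.17e-07 and 1.41e-05) lost with an adjusted p = 0.157, 0.12 and 0.158 with an estimated correlation and lost after rescaling (adjusted p = 0.0874, 0.064 and 0.159). Ndufs3, a complex I subunit, fell by 0.80, 0.73 and 0.60 (SE 0.15), also lost after rescaling (0.37, 0.42 and 0.40, SE 0.26). Housekeeping genes (14 measured) had 4, 4 and 2 lower and 0 higher (5, 4 and 1 lower adjusted over the list alone), called with LPS and PAM3CSK4 (adjusted p = 0.00547 and 0.00943), lost with an adjusted p = 0.95 and 0.938 with an estimated correlation, and their medians of −0.32 and −0.17 turned to 0.11 and 0.13 after rescaling, where the calls were lost (adjusted p = 0.0744 and 0.482). With zymosan they were called lower with the set term (adjusted p = 0.00465) and the replicate block (adjusted p = 0.0283) but not without (adjusted p = 0.0556, and 0.991 with an estimated correlation). Cholesterol synthesis genes (20 measured; 1, 0 and 0 higher and 5, 5 and 3 lower; 1, 0 and 0 and 4, 5 and 3 adjusted over the list alone) were not called (adjusted p = 0.131, 0.161 and 0.329; with PAM3CSK4 0.0186 with the set term, and 0.938 with an estimated correlation without it), nor were LXR targets (13 measured; 1, 2 and 1 higher and 4, 1 and 1 lower; 1, 2 and 2 and 4, 2 and 2 adjusted over the list alone; adjusted p = 0.141, 0.43 and 0.876). Both lists were called lower with LPS by the replicate block (adjusted p = 0.0309 each), without paired numbers. Dhcr7, the last enzyme of cholesterol synthesis, fell by 1.34, 1.20 and 0.97, and Ch25h, which makes 25-hydroxycholesterol, rose by 0.82, 0.92 and 1.07. Genes of Gi, cAMP and receptor desensitisation (25 measured) had 2, 3 and 2 higher and 5, 4 and 4 lower (2, 3 and 3, and 5, 5 and 5 adjusted over the list alone) and were not called (adjusted p = 0.0587, 0.061 and 0.211), but were called higher with LPS after rescaling (adjusted p = 0.00363), where the median of −0.23 turned to 0.13. The set term called them lower with each (adjusted p = 0.00606, 0.00105 and 0.0308) and the replicate block with PAM3CSK4 (adjusted p = 0.047), whereas without either they had an adjusted p = 0.705, 0.938 and 0.991 with an estimated correlation. The block called this list lower with LPS too (adjusted p = 0.0354), without paired numbers. Pde4b, a cAMP-degrading enzyme, rose by 2.14, 2.05 and 2.18. Dectin-1, Syk-Card9 and NFAT genes (17 measured) had 1, 0 and 1 higher and 1, 3 and 1 lower (1, 0 and 1, and 1 each adjusted over the list alone) and were not called (adjusted p = 0.675, 0.64 and 0.486), but were called higher after rescaling (adjusted p = 9.46e-05, 0.00177 and 0.00015), where the LPS median of −0.06 turned to 0.31, with an adjusted p = 0.351, 0.546 and 0.324 with an estimated correlation without rescaling. Clec4e, a fungal lectin receptor, rose with LPS and zymosan by 0.82 and 0.85, and with PAM3CSK4 did not pass (adjusted p = 0.0727) but was called with the replicate block, with the set term and after rescaling (adjusted p = 0.0224, 0.0373 and 0.0144). Pnoc, the nociceptin precursor gene, was listed at 0 in all 8 PBS and morphine libraries and at 0.155 to 1.86 FPKM in the 12 TLR agonist libraries.

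The 7 libraries stood apart from the other 13 in every group. Lower depth that adds noise to low genes only would leave high genes alike. Of the genes with a mean of at least 50 FPKM, 77.3% differed between the sets. A few genes taking most of the reads would shift all others by 1 factor, and 89.6% as many genes differed after rescaling. Both shares are raised by an amount not measured, because the sets were taken from these same values, so neither explanation is excluded. A batch of culture, library preparation or sequencing stays open, as the labels name none, and no biological explanation was tested.

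More genes fell than rose with the TLR agonists. The genes called higher with LPS held 7.14% of the FPKM total with PBS and 23.3% with LPS, a rise of 16.1 points, beside a median fall of 22.9% over all genes. With PAM3CSK4 the rise was 16 points beside a median fall of 16.9%, and with zymosan 13.9 points beside 11.8%. Points of the total and relative falls are unlike measures, so no shortfall can be read from them. A larger share held by induced transcripts, which lowers all others, cannot be told apart from a true excess of falls, because the table holds no counts and no measure of total RNA per cell. Every cell cycle gene fell with and without rescaling, so that part did not depend on it.

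No gene was called with morphine. A spread between libraries that hides 2-fold changes stays open. With the library-set term 97.1% of the intervals lay within 1 log2 unit of 0, but the term was taken from that spread and so narrows them. Without it 76.2% did, and 48.6% of simulated 2-fold and 93% of 4-fold changes were recovered. On the log2(FPKM + 1) scale a 2-fold change of a low gene is also under 1 unit. The library sets, held unequally by the 2 groups, as what hides the change are argued against by the 0 genes called with the term. Changes of 2-fold or less stay open, as does the time of exposure, which is not given in the sources used here.

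Other splits of the 8 libraries of each comparison into 4 and 4 were counted, 35 in all with the real one. For morphine against PBS, without and with the set term, the real count was 0, so that all 35 had to reach it and the splits say nothing about chance (highest other 2 and 5). Where only the real split (1 of 35) gave as many genes, chance is less likely but not excluded, since 35 splits give no smaller share. This held for LPS against PBS (2866, highest other 0, with the term 4458 and 1), PAM3CSK4 against LPS (3 and 1, with the term 11 and 1) and zymosan against LPS (8 and 1, with the term 96 and 2). For PAM3CSK4 against LPS, 0 genes were called with a pseudocount of 0.1 FPKM, no filter or only the 2 groups compared, so chance stays open there. The splits also exchange libraries freely, although 19 of 20 correlated best with a library of their own number. In the other 4 comparisons the replicate numbers paired the libraries by the rule used. There the real split was also compared with those that part every pair, 8 in all, too few for a share under 0.05. This comparison was added after the fits had been run. The real count and the highest of the others were 2496 and 0 for PAM3CSK4 against PBS (with the term 4513 and 0), 1670 and 0 for zymosan (3366 and 0) and 2256 and 0 for morphine against LPS (4111 and 24). For zymosan against PAM3CSK4 they were 0 and 0, where all 8 had to reach the real count, 8 and 0 with the term, and 8 and 0 with the replicate block. The 27 splits with a pair on 1 side differed by mixing the numbers, and called up to 0, 0, 2644 and 1 genes in these comparisons, in this order, and with the term up to 0, 1, 435 and 2. The split with 2644 had all 4 libraries of the smaller set on 1 side. For morphine against LPS, 2 of all 35 splits thus gave as many genes as the real one, a share over 0.05. The planned count therefore left chance open there, whereas with the term 1 of 35 did so.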
